A study of Homo sapiens with 2 samples.

How the data were processed

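RNA sequencing libraries were analysed from 2 samples of SAS, an oral cancer cell line, with 1 library per group. Per the labels, 1 sample stably carried the lentiviral plasmid pLKO.AS2 with the ASC sequence and the other the plasmid without it, and both were grown in DMEM with serum, G418 and puromycin. The group of the control sample was taken from its genotype label and that of the ASC sample from its vector label, since its genotype label names the cell line in place of ASC. Per the labels' protocols, RNA was extracted with TRIzol, poly(A) RNA was used and libraries were made with a TruSeq kit that does not mark strand. Reads of a gene and of an overlapping or antisense partner therefore cannot be told apart.

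The deposited table lists 134092 transcripts with their position and gene name. Per the file headers it holds estimated counts of reads per transcript, which are fractional and not scaled to depth, and RPKM values (reads scaled to transcript length and library depth), both for each library. The genome build is hg38 per the submitters' processing notes, and the aligner, the quantifier and the annotation release are not given in the sources used here. Transcript identifiers were checked against GENCODE release 29, in which 98.4% had the same version and 99.9% the same identifier. Starts of those with the same version were equal and stops lay 1 base past the annotated end, so printed ends are the stop minus 1. In the deposited RPKM, reads were divided by transcript length and by 1 constant per library. The listed reads are 88.1% of this constant in the ASC library and 87.4% in the control library. In 285 lines a spreadsheet had turned the gene name into a date. Of these, 284 names were restored through the transcript identifier, which gave 24124 genes in place of 24120 names.

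RPKM was summed over the transcripts of each gene, and genes with at least 1 RPKM in either library were compared (12471 genes, 51.7% of those in the table). The log2 ratio is that of the ASC over the control library with a pseudocount of 1 RPKM, with no further scaling. Genes with an absolute log2 ratio of at least 1 were counted. With 1 library per group there is no test between conditions and no p-value. For named genes, a 95% interval of the ratio of reads scaled to library depth was computed from the rounded estimated reads with the exact (Clopper-Pearson) binomial method. It covers counting error only, since reads are not independent molecules and estimated reads of similar transcripts carry further error. The 31426491 listed reads of the ASC library and 31289581 of the control library give 12154 and 12205 genes of at least 1 RPKM.

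The 42 gene lists, the design and most alternatives were fixed before the data were examined. Of the 772 distinct genes listed, 702 were found, with older symbols matched through a gene name table, and 32 are in more than 1 list. For lists with at least 5 compared genes, the median log2 ratio was ranked among 10000 random lists of the same size, drawn from the compared genes and matched on mean expression in 20 bins. A percentile below 2.5 or above 97.5 was called outside the random range. Named genes are PYCARD, the 12 genes with the largest and the 12 with the smallest log2 ratio among genes of at least 5 RPKM in either library, and up to 4 genes per list with the largest absolute log2 ratio. Pseudogenes, readthrough, antisense and unnamed loci and genes on several chromosomes were left out of the 12 on each side. PYCARD is in no list and counts among the 12 largest. Some genes that this rule names are not reported here.

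The procedure was tested on simulated data for the ASC over control comparison with 12471 genes. Of 50 genes each given a true fold of 1.5, 2, 3 and 4, the share counted as 2-fold was 0%, 14%, 90% and 100%. A list step run on 200 random lists placed 10 outside the range, and 49 of 50 lists shifted by 0.3 were placed above it. The random lists were drawn from the same genes as those they were ranked against. Their share outside was thus set in advance, and it checks the calculation only.

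Alternatives were pseudocounts of 0.1 and 3, no filter on low values, a filter at 5 RPKM, centring on the median, TMM scaling of the rounded estimated counts with edgeR, counts scaled to library depth only (CPM), the highest transcript in place of the sum, and protein-coding genes only. Further ones were fold thresholds of 1.5 and 4, random lists without matching, and list means. Chosen after seeing the data were 3 more: removal of a trend on transcript GC content, removal of a trend on transcript length, and subtraction of the median of the 50 nearest genes on the chromosome. Also written after the gene values had been seen were 4 second gene lists, of chaperone, interferon-gamma, STAT3 and glucocorticoid genes. Shifts along chromosomes were measured as medians of consecutive windows of 50 genes against 1000 shuffles of the gene order. Analyses used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for the TMM factors only, which were 1.00 and 0.998.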

Results

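Gene expression was measured in SAS, an established human oral cancer cell line, carrying a stable vector that expresses ASC or the same vector without it. ASC is the adaptor protein encoded by PYCARD. It joins inflammasome sensors to caspase-1. The comparison asks which genes differ between SAS cells with and without added ASC. Each group had 1 library, the ASC library with 31426491 listed reads and the control vector library with 31289581. A total of 12471 genes reached at least 1 RPKM in either library. Values are given as ASC library against control library, in RPKM, and log2 ratios are on the log2(RPKM + 1) scale, which understates differences of low genes. Counts of genes past or within 2-fold refer to this scale, so a low gene can differ by over 2-fold in plain RPKM and not be counted. No library was repeated, so no difference below has a replicate check, and the intervals cover counting error only.

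PYCARD itself stood at 266.5 RPKM in the ASC library against 1.36 RPKM in the control library, a 196-fold difference, with 9256.4 against 41 estimated reads. Its log2 ratio was 6.83, the largest of all genes compared, and its log2 ratio of reads scaled to library depth was 7.82 (95% interval 7.38 to 8.30). The direction matches the labels of both libraries. PYCARD (ENSG00000103490.13) lies on the minus strand of chromosome 16, from 31201485 to 31203450 in hg38. Of its 4 annotated transcripts, ENST00000247470.9 held 96.7% of the PYCARD reads in the ASC library and 64.2% in the control library.

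Apart from PYCARD, the libraries were close. At least 2-fold higher in the ASC library were 77 genes, and 33 genes were at least 2-fold lower, together 0.882% of the genes compared. These counts depend on the scale, with 160 higher and 127 lower at a pseudocount of 0.1. With CPM, where the filter and pseudocount are also in CPM and 13539 genes are compared, the counts were 121 and 65. Of those, 73 and 28 were also counted on the RPKM scale. A pseudocount of 3 gave 34 and 9. At 4-fold the counts were 9 and 2. Within 1.5-fold lay 95.8% of genes, with a median log2 ratio of 0.01. Protein-coding genes made up 71 of the 77 and 25 of the 33. Libraries simulated with counting error alone gave between 0 and 3 genes past 2-fold in 100 simulations. Such libraries leave out error in assigning reads to transcripts and differences between library preparations.

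**Figure D1:**
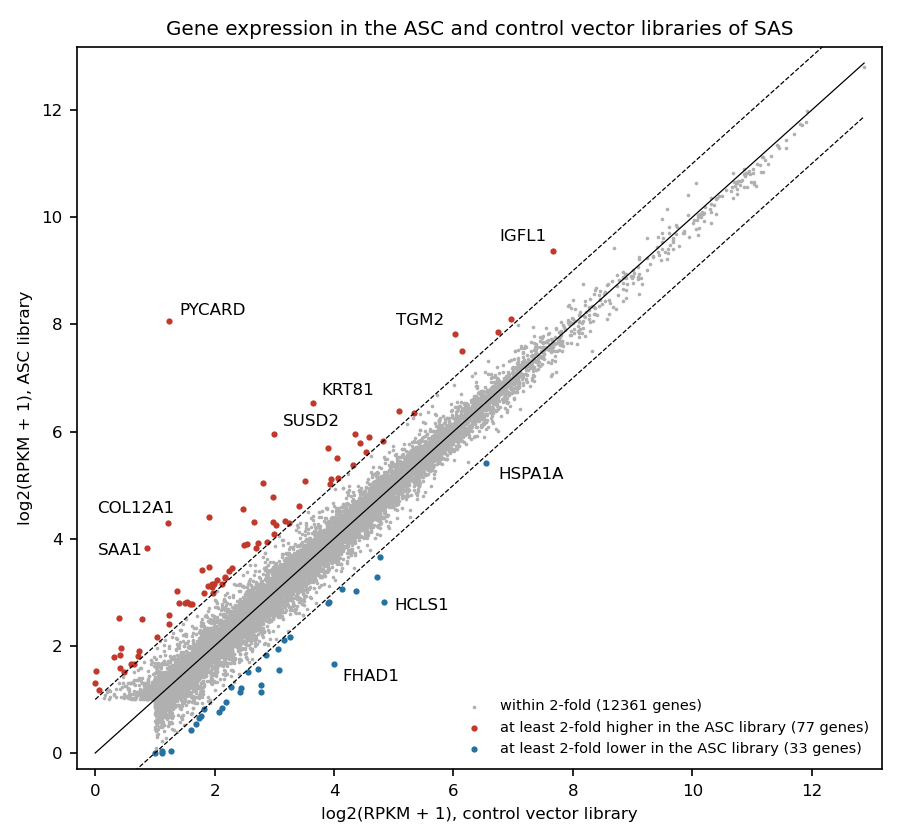
Expression of the 12471 compared genes, with log2(RPKM + 1) in the control vector library on the x axis and in the ASC library on the y axis. Each point is a gene, the solid line marks equal values and the dashed lines 2-fold differences, with 77 genes above (red) and 33 below (blue), and PYCARD lies farthest from the line.

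COL12A1, a fibril-associated collagen chain, stood at 18.5 against 1.32 RPKM, with a log2 ratio of 3.07. SUSD2, a membrane protein with a sushi domain, stood at 60.6 against 6.98 RPKM. The acute-phase gene SAA1 stood at 13.1 against 0.834 RPKM, with 289.6 against 18.4 reads. The hair keratin gene KRT81 stood at 91.3 against 11.5 RPKM. CLIC3 stood at 20.2 against 2.74 RPKM, and the kinase gene SGK1 and LIMCH1 followed with log2 ratios of 2.23 and 2.08. Among abundant genes, TGM2, which encodes tissue transglutaminase, stood at 225.7 against 63.9 RPKM, and IGFL1 at 658.3 against 203.2 RPKM. GGT5 and SLPI, the secretory leukocyte protease inhibitor, had log2 ratios of 1.80 and 1.79. Reads of KRT81 and SAA1 can be shared with near-identical neighbours such as KRT86 and SAA2, so their levels are uncertain.

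The genes with the smallest ratios were lower by less. FHAD1, which encodes a protein with a forkhead-associated domain, stood at 2.17 RPKM in the ASC library, 6.90-fold lower than in the control library, with a log2 ratio of -2.33. HCLS1, best known from blood cells, stood at 6.05 against 27.5 RPKM. TNNI2, IFT81 of the ciliary transport machinery and the integrin gene ITGB8 had log2 ratios of -1.43, -1.34 and -1.16. The inducible HSP70 gene HSPA1A stood at 41.8 against 91.9 RPKM, though its reads can be shared with its near-identical copy HSPA1B. FNBP1L, CLEC2B, AKAP9 and IAH1 lay between -1.12 and -1.10, though AKAP9 and IAH1 came to -0.89 and -0.96, short of 2-fold, after subtraction of the median of neighbouring genes.

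**Figure D2:**
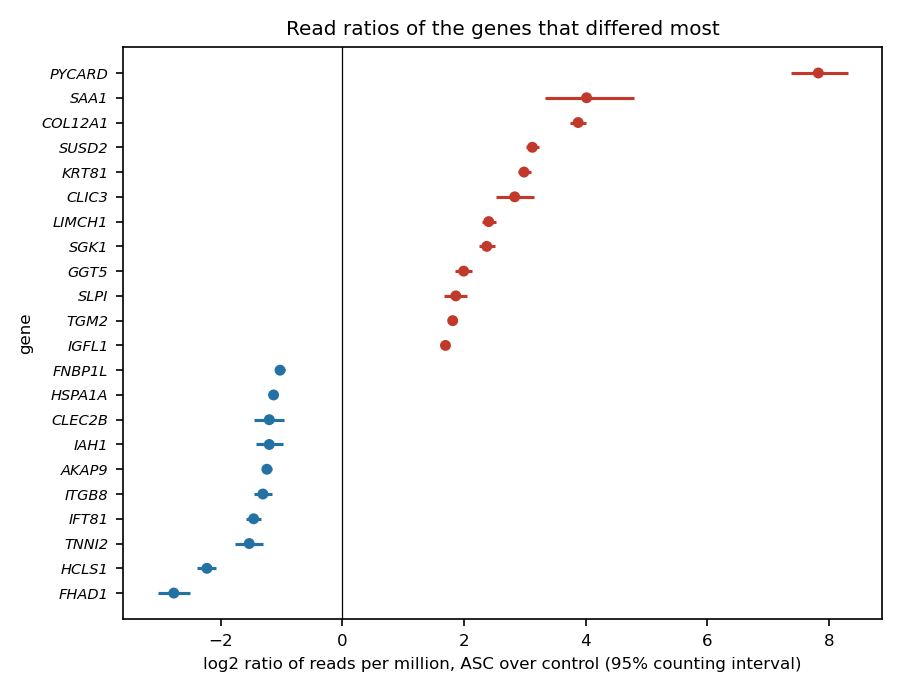
Log2 ratios of reads scaled to library depth (CPM), ASC over control, for PYCARD and other genes named by the rule of largest and smallest ratio, with 95% exact counting intervals as bars. PYCARD stands at 7.82, the other higher genes (red) lie above 1.6 and the lower genes (blue) below -1.0.

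Of 42 gene lists, 36 had enough compared members for a percentile of their median among 10000 random lists matched on expression. The medians of 14 lists lay above the central 95% of random medians and those of 5 below it, where chance alone would place 1.8 lists outside. Most members of these lists differed by less than 2-fold, and 19 of the 77 higher genes and 2 of the 33 lower genes belonged to any list. Members of a list are not independent, and the percentiles describe these 2 libraries.

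**Figure D3:**
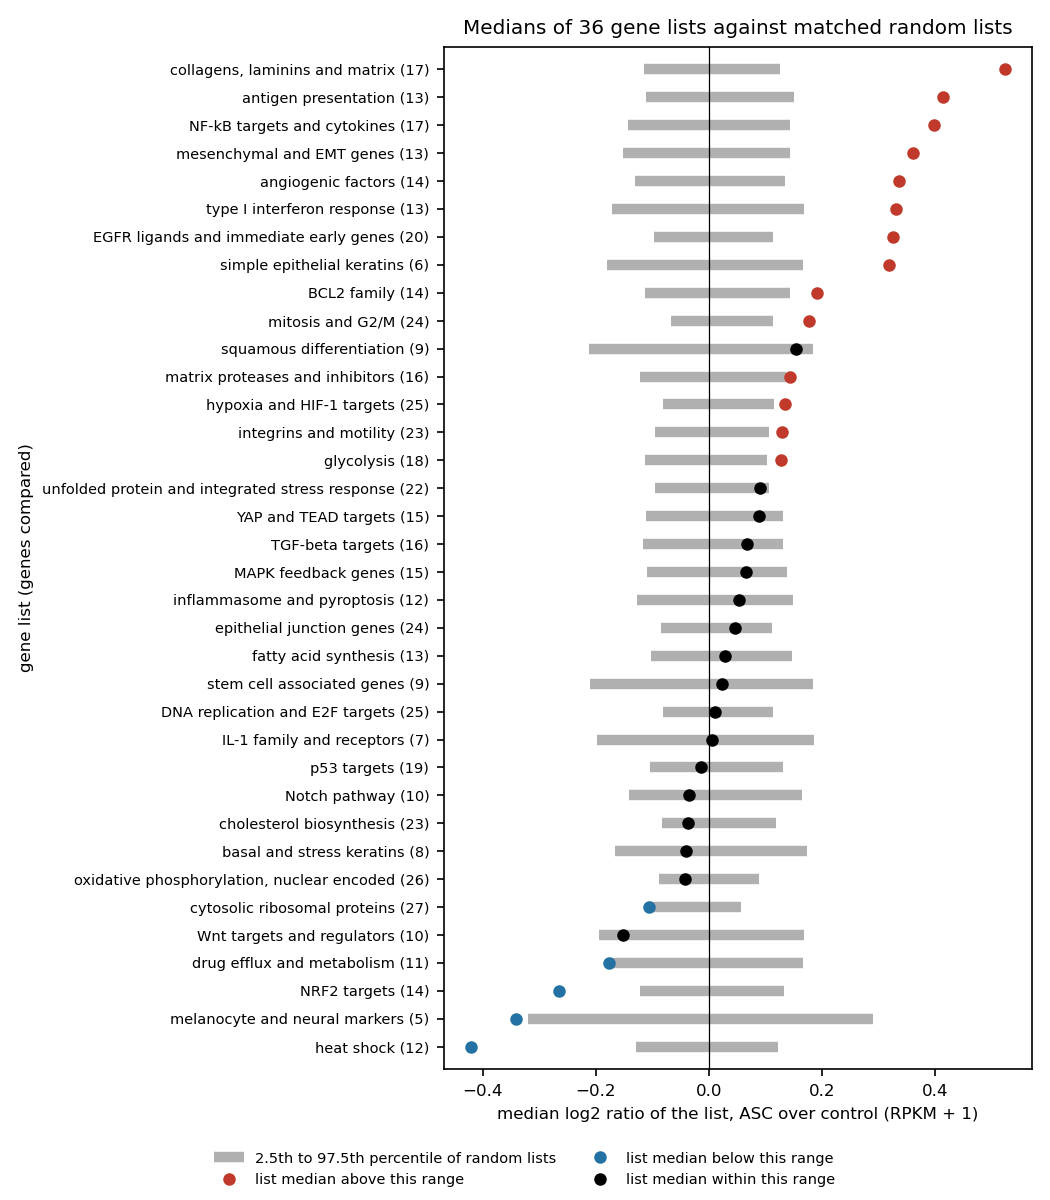
Median log2 ratio, ASC over control, of each of the 36 gene lists (points), with the number of genes compared in parentheses and the central 95% of medians of matched random lists as grey bars. The collagen and matrix list lies highest at 0.52 and the heat shock list lowest at -0.42.

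Of 12 compared inflammasome and pyroptosis genes, none was 2-fold higher or lower, and the median of 0.05 lay at percentile 72.2. The sensor gene NLRP1 stood at 13.2 against 12.3 RPKM and CARD8 at 5.76 against 6.37, while NLRP3, AIM2, NLRC4 and MEFV were under 1 RPKM in both libraries and were not compared. The caspase gene CASP1 stood at 8.18 against 4.98 RPKM, a 1.64-fold difference, with a log2 ratio of reads of 0.77 whose interval starts at 0.53, and CASP4 at 50.3 against 35.1 RPKM. CARD16 stood at 1.77 against 0.947 RPKM, with 40.9 against 22.2 reads and an interval of 0.12 to 1.72 for its log2 ratio of reads. Estimated reads of CASP1 and CARD16 were fractional, so these differences may not be separate if the genes share reads. Likewise, none of 7 compared IL-1 family and receptor genes passed 2-fold, with a median of 0.01 at percentile 51.2. In that list IL1RL1 had a log2 ratio of 0.54 and IL18BP one of -0.28.

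The NF-kB, type I interferon and antigen presentation lists lay above the random range, with most members within 2-fold. Of 17 compared NF-kB targets and cytokines, 16 had log2 ratios above 0, 3 were at least 2-fold higher and 14 were within 2-fold on this scale, among them CXCL8 at 3.03 against 1.23 RPKM and CXCL2, 2.21-fold higher in plain RPKM. The median of 0.40 lay above every random list (percentile 100). IL6 stood at 5.94 against 1.83 RPKM, the chemokine gene CXCL1 at 3.50 against 1.05, the adhesion gene ICAM1 at 18.6 against 8.51 and LIF at 18.1 against 9.41. Of 23 type I interferon response genes in the data, 13 reached 1 RPKM and were compared. Of these, 12 lay above 0, 2 were at least 2-fold higher and 11 were within 2-fold, with a median of 0.33 at percentile 100. Those 2 were IFIT2 and IFIT1, with log2 ratios of 1.36 and 1.10, and IFIT3 followed at 0.88. These IFIT genes lie close together on chromosome 10. MX1 was low at 1.04 against 0.515 RPKM, and IFI6 had a log2 ratio of -0.02. Genes too low to compare went both ways, with OAS1 at 0.445 against 0.741 and OASL at 0.282 against 0.0825 RPKM. All 13 compared antigen presentation genes lay above 0 and within 2-fold, with a median of 0.41 at percentile 100. The immunoproteasome genes PSMB10 and PSMB9 had log2 ratios of 0.72 and 0.62, and the class I genes HLA-C and HLA-B 0.60 and 0.54.

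Extracellular matrix genes had the highest median, 0.52 at percentile 100, among the 36 lists with a percentile. Of 17 compared collagen, laminin and matrix genes, 4 were at least 2-fold higher, none was 2-fold lower and 13 were within 2-fold. Beside COL12A1 these were COL5A2 (9.70 against 2.45 RPKM), fibronectin FN1 (180.5 against 69.8 RPKM) and tenascin TNC (5.83 against 2.06 RPKM). The mesenchymal and EMT list, which also holds FN1 and TNC, had 4 of 13 genes higher, 9 within 2-fold and a median of 0.36 at percentile 100. In this list 10 genes lay above 0 and 3 below, SNAI2, ACTA2 and S100A4. The regulator genes SNAI1 and TWIST2 had log2 ratios of 0.40 and 0.30. ZEB1, ZEB2, TWIST1, PRRX1 and FOXC2 were under 1 RPKM in both libraries and were not compared. LOXL2, a collagen crosslinking enzyme, stood at 44.7 against 15.6 RPKM. CDH11 was low, at 1.27 against 0.046 RPKM. The percentile of this list was 86.4 when only genes of at least 5 RPKM were kept and 93.0 with no filter.

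Epithelial junction genes were close in both libraries. Of 24 compared, none was 2-fold higher or lower, 16 lay above 0 and the median of 0.05 was at percentile 75.1. PKP1 and DSC3, of the desmosome, had log2 ratios of -0.66 and -0.48, while OCLN and PKP3 had 0.42 and 0.38. CDH1 stood at 82.6 against 65.6 RPKM, with a log2 ratio of 0.33. In the simple epithelial keratin list all 6 genes lay above 0, with a median of 0.32 and percentile 99.9 (96.9 with no filter). Only KRT81, a hair keratin gene placed in that list, passed 2-fold, and KRT7 had a log2 ratio of 0.05. KRT8 stood at 1136 against 763 RPKM and KRT18 at 1363 against 967.1 RPKM. In the basal and stress keratin list the median was -0.04 at percentile 29.3, but it lay below the random range at 0.36 with a filter at 5 RPKM and at 2.21 with the highest transcript. None of its 8 genes passed 2-fold, with COL17A1 at -0.64, KRT5 at -0.44 and KRT14 at 0.42. Of 9 squamous differentiation genes, 5 lay above 0 and 4 below, with CSTA at 58.9 against 90.2 RPKM. At least 2-fold higher were 2, S100A9 (230.5 against 106.6 RPKM) and the protease inhibitor gene PI3 (log2 ratio 1.16, or 0.98 after subtraction of neighbours). PI3 was low, at 1.99 against 0.339 RPKM with 41 against 7 reads. LCN2 and S100A7 were also low, at 1.99 against 0.680 and 1.58 against 0.642 RPKM. The percentile of this list was 95.5, and it passed the range at 97.9 with a pseudocount of 3, 99.3 with CPM and 97.6 with the highest transcript, and with means as well.

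The matrix protease and motility lists had positive medians that depended on the settings. Of 16 protease and inhibitor genes, 1 was 2-fold higher, none was 2-fold lower, and the median of 0.14 lay at percentile 98.0. ADAM12 had a log2 ratio of 0.94 (3.31 against 1.25 RPKM), the urokinase gene PLAU 0.54 and PLAT -0.57. Of 23 integrin and motility genes, ITGB8 was 2-fold lower, none was 2-fold higher, and the median of 0.13 lay at percentile 99.2. L1CAM, PODXL and ITGA3 had log2 ratios of 0.83, 0.53 and 0.44. Both list medians returned inside the random range, at percentiles 87.6 and 94.9, when the median of neighbouring genes on the chromosome was subtracted from each gene. The motility list also fell inside it, at 84.4, with means in place of medians. The protease list fell inside it under 5 further settings, lowest at 39.0 with the highest transcript in place of the sum.

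The hypoxia and glycolysis lists had small positive medians. Of 25 compared hypoxia and HIF-1 target genes, 18 lay above 0, 1 was 2-fold higher, and the median of 0.13 lay at percentile 99.1. That 2-fold higher gene is also the one counted in the protease list and is among those of the TGF-beta list. SLC2A1 and HK2 are in both the hypoxia and glycolysis lists. PLOD2, BHLHE40 and the glucose transporter gene SLC2A1 had log2 ratios of 0.53, 0.51 and 0.49, while ADM, PFKFB3 and MXI1 had -0.44, -0.43 and -0.37. Of 18 glycolysis genes, 15 lay above 0 and none passed 2-fold, with a median of 0.13 at percentile 99.2 (96.9 without matching on expression). SLC2A3 (4.91 against 2.24 RPKM) and ENO2 had the largest ratios there, 0.87 and 0.58. The 26 nuclear genes of oxidative phosphorylation had a median of -0.04 at percentile 19.2, none past 2-fold, with ATP5G1 at -0.46.

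The EGFR ligand and angiogenic factor lists also lay above the random range, with members on both sides of 0. Of 20 EGFR ligand and immediate early genes, 14 lay above 0, AREG alone was 2-fold higher and the median of 0.33 lay at percentile 100. The amphiregulin gene AREG stood at 274.2 against 123.6 RPKM, and EREG and HBEGF at 10.4 against 5.42 and 24.3 against 14.8 RPKM, while EGR2 and FOS had log2 ratios of -0.44 and -0.26. Reads of AREG can be shared with a near-identical copy in some annotations. Of 14 angiogenic factor genes, 10 lay above 0, none passed 2-fold and the median of 0.34 lay at percentile 100. THBS1, which is also in the matrix list, stood at 683.7 against 409.6 RPKM. It encodes an inhibitor of angiogenesis, so the median of this list has no single direction of effect. PDGFB and VEGFA had log2 ratios of 0.63 and 0.45. PDGFA had 0.53, or 0.21 after subtraction of neighbours, and PDGFC had -0.36. In the MAPK feedback list (15 genes, percentile 78.2) DUSP4 was 2-fold higher and DUSP2 had a log2 ratio of -0.63. This list passed the range at 99.1 with a filter at 5 RPKM, 99.7 with the highest transcript and 98.6 with means. In the TGF-beta target list (16 genes, percentile 82.3), 3 genes were 2-fold higher, among them TGFB2 and INHBA, and ID2 had a log2 ratio of -0.99 (0.912 against 2.80 RPKM).

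The mitotic and BCL2 family lists had small positive medians. Of 24 mitosis and G2/M genes, 18 lay above 0 and none passed 2-fold, with a median of 0.18 at percentile 99.9. KIF23 and CENPF had log2 ratios of 0.42 and -0.59, while AURKA and UBE2C had 0.54 and 0.41, or 0.34 and 0.21 after subtraction of neighbours. The 14 BCL2 family genes had a median of 0.19 at percentile 99.7, none past 2-fold. The list mixes survival and death genes, so its median has no direction for survival. The survival gene BCL2L1 stood at 137.4 against 91.2 RPKM, a log2 ratio of 0.59, or 0.48 after subtraction of neighbours. The death genes PMAIP1 and BBC3 had 0.47 and 0.32, and BCL2L11 had -0.38. With means in place of medians the mitosis and BCL2 family percentiles were 96.9 and 96.4. DNA replication and E2F targets (25 genes) and p53 targets (19 genes) lay at percentiles 42.5 and 30.9, with none past 2-fold. TYMS had a log2 ratio of 0.64 and CDT1 of -0.56, and MDM2 and BTG2 had 0.44 and -0.50.

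The heat shock list had the lowest median of the lists with a percentile. All 12 compared heat shock genes lay below 0, with HSPA1A alone 2-fold lower, 11 within 2-fold and a median of -0.42, below every random list (percentile 0). HSPB1 stood at 180.8 against 316.9 RPKM, HSPH1 at 63.4 against 106.5 and HSPA1B at 42.3 against 74.5. Of 14 NRF2 targets, the antioxidant response genes, 13 lay below 0 and none passed 2-fold on the log2(RPKM + 1) scale, with a median of -0.26 at percentile 0. Its largest differences were in GPX2 (-0.69, but 2.92-fold lower in plain RPKM), UGT1A6 (-0.56), the cystine transporter gene SLC7A11 (-0.47) and GCLC (-0.40). All 27 cytosolic ribosomal protein genes lay below 0 and within 2-fold, with a median of -0.11 at percentile 2.05, up to 6.95 under other settings. RPL30 and RPL8 stood at -0.32, or -0.13 and -0.16 after subtraction of neighbours, and RPL3 at -0.28. The 11 drug efflux and metabolism genes had a median of -0.18 at percentile 2.17 (up to 3.77 under other settings), with GSTM3 at -0.54, ABCC5 at -0.47 and ALDH1A3 at 0.60.

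Further pathway lists lay inside the random range with no member past 2-fold on the log2(RPKM + 1) scale, though some left it under other settings. In plain RPKM SOX2, LEF1 and WNT10A were 3.05-fold, 2.19-fold and 2.06-fold lower. Of 22 unfolded protein and integrated stress response genes, CHAC1 and PPP1R15A had log2 ratios of 0.73 and 0.69 (percentile 95.3). This list passed the range at 97.6 with CPM, 98.1 with the highest transcript, 97.7 with means and 100 after subtraction of neighbours. Cholesterol biosynthesis (23 genes) and fatty acid synthesis (13 genes) lay at percentiles 12.7 and 51.2, with ACSS2 at 0.57 and FDFT1 at -0.34, or -0.19 after subtraction of neighbours. Wnt targets and regulators (10 genes) lay at 6.51, with WNT10A at -0.85 and LEF1 at -0.60, and fell below the range at 1.71 with the highest transcript, 1.70 with means and 2.33 after subtraction of neighbours. The Notch pathway (10 genes) lay at 24.5, with NOTCH3 at 0.72 and JAG1 at -0.53. YAP and TEAD targets (15 genes) lay at 89.8 (97.9 after subtraction of neighbours), with LATS2 at 0.59, and stem cell associated genes (9 genes) at 62.5, with SOX9 at 0.64 and SOX2 at -0.61.

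Lists with fewer than 5 compared genes have values only. All 4 metallothionein genes compared were higher but within 2-fold, with MT2A at 1596 against 1061 RPKM and MT1X at 74.7 against 39.1 RPKM. The histone gene HIST2H2AC had a log2 ratio of -0.52. Markers of other cell types were mostly below 1 RPKM in both libraries. Compared were FBLN1 of the fibroblast list (log2 ratio 0.22), CDH5 of the endothelial list (0.53), and CORO1A (0.74) and CD68 (-0.10) of the leukocyte list. The 5 melanocyte and neural genes had a median of -0.34 at percentile 1.96, with MAP2 at -0.43 and TUBB3 at 0.60. This list lay within the range at 3.4 with a pseudocount of 0.1, 5.59 with no filter, 25.1 with CPM and 13.6 with means. Of 13 mitochondrial mRNAs in the deposited values, only MT-CO1 (1.21 against 1.23 RPKM) and MT-CO2 (1.15 against 1.14 RPKM) reached 1 RPKM.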

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

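The corrections for GC content, transcript length and neighbouring genes were chosen after the data were seen. No paired analysis was possible because each group has 1 library. PYCARD stayed far higher in the ASC library under every setting run, with a log2 ratio of 7.52 at a pseudocount of 0.1 and 5.95 at 3, which follows from the scale. The number of higher genes, 77, became 160 at a pseudocount of 0.1, 34 at 3, 121 with CPM, 297 at 1.5-fold and 9 at 4-fold. The number of lower genes, 33, became 127, 9, 65, 226 and 2 under the same settings in the same order, and 17 with a filter at 5 RPKM, where fewer genes are compared. With CPM more genes are compared, 13539, since its filter is in CPM. After subtraction of the median of neighbouring genes, 72 of the 77 and 25 of the 33 were still counted. Between 17 and 21 lists lay outside the random range. The lists of NF-kB, interferon, antigen presentation, hypoxia, matrix, EGFR ligand, angiogenic, heat shock and NRF2 genes stayed outside under all 14 settings run. Integrins and motility came to percentile 84.4 with means and 94.9 after subtraction of neighbours. Matrix proteases came to 94.7 at a pseudocount of 3, 79.6 with no filter, 93.3 at 5 RPKM, 96.6 after GC correction, 87.6 after subtraction of neighbours, and 39.0, below the middle, with the highest transcript. The mesenchymal list came to 93.0 with no filter and 86.4 at 5 RPKM. The lists of stress response, Wnt, YAP, MAPK feedback, basal keratin and squamous genes left the random range only under some settings. The cause of these gains and losses was not tested. Of 1943 values for named genes under other settings, 4, from 2 genes near 0, had the opposite sign. The median of all genes moved by less than 0.1 in every setting. Depth limits low genes, such as HIST2H2AC, whose interval of -2.58 to 0.11 includes 0, and the lack of repeated libraries limits every comparison.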

Other observations

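Tests chosen only after their result was seen are those on markers of other cell types, on random gene order and on the correlation of adjacent windows. The second gene lists were written after the gene table had been looked at, though before their medians were computed. The corrections for GC content, length and neighbouring genes were also added after the data were seen.

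In a second list of STAT3 response genes all 14 compared genes lay above 0 and 1 was 2-fold higher, with a median of 0.37 and SERPINA3 and SBNO2 close to 0 at 0.06 and 0.04. SAA2 stood at 4.70 against 0.316 RPKM, the suppressor of cytokine signalling gene SOCS3 at 14.8 against 7.73 and PIM1 at 81.1 against 46.6. In a list of interferon-gamma response genes 9 of 11 lay above 0 and 1 was 2-fold higher, with a median of 0.43, among them IRF1 (45.4 against 23.7 RPKM, also in the STAT3 list) and APOL1 (1.87 against 0.399 RPKM), while GBP2 and JAK2 had log2 ratios of -0.02 and -0.19. In a list of glucocorticoid response genes 6 of 9 lay above 0 and none passed 2-fold, with TSC22D3 at -0.10 and PER1 at -0.20. Chosen after their values were seen, the complement gene C3 stood at 7.16 against 1.58 RPKM, IL7R at 18.9 against 5.32, KISS1 at 60.8 against 19.5 and IL11 at 5.85 against 2.01. Also chosen afterwards, the BMP target genes ID1 and ID3 had log2 ratios of -0.66 and -0.87, like ID2 at -0.99, in the TGF-beta list where INHBA and TGFB2 were higher.

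Neighbouring genes differed together along several chromosomes. Of 239 windows of 50 consecutive genes, 33 had a median below -0.09 and 14 above 0.11, the limits that hold 99% of windows in shuffled gene order. On chromosome 7 the first 100 genes (135853 to 26213356) had a median of 0.29 with 84.0% above 0, and the next 500 genes (26291895 to 151076527) a median of -0.16 with 78.4% below 0. On chromosome 2, 500 genes from 38814 to 132646559 had a median of -0.20 with 83.8% below 0. On chromosome 19, 300 genes from 60951 to 15200981 had a median of -0.17. On chromosome 20, 250 genes from 25006230 to 64287821 had a median of 0.20 with 80.8% above 0, a stretch that holds TGM2, SLPI, BCL2L1 and AURKA. After subtraction of their neighbours these 4 genes had log2 ratios of 1.60, 1.63, 0.48 and 0.34, against 1.80, 1.79, 0.59 and 0.54 before.

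Random placement cannot account for these windows, since 47 lay beyond the limits and no shuffle gave more than 10. A GC content trend is argued against too, as 46 windows lay beyond the limits after its removal. Adjacent windows on a chromosome correlated with r = 0.712 over 216 pairs, against at most 0.271 in the shuffles, which restates these stretches and would follow from any cause that acts on them. Of the 33 genes lower by 2-fold, 0% lay in windows with a median of -0.2 or less, which says little because only 10 of the 239 windows are that low, and 25 of the 33 were still counted after subtraction of neighbours. DNA was not measured here. A copy-number difference between the 2 separately selected lines and regulation over the same long stretches therefore cannot be told apart, and both stay open.

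After subtraction of neighbouring genes 12 of the 14 lists above the random range stayed above it, after removal of a GC trend 13, and after removal of a length trend 14, which argues against each of these as the whole cause. A large share of fibroblasts, leukocytes or endothelial cells is argued against by low markers such as COL1A1 (0.353 against 0.0941 RPKM) and PTPRC (0.0542 against 0). VWF was the highest of the 8 tested at 0.584 against 0.840. The limits of this test were set after the values were seen. Of the fixed marker lists FAP (0.516 against 0.0364 RPKM) and PDGFRB (0.212 against 0.0984) were higher at low levels. FBLN1 (27.5 against 23.5 RPKM), CD68 (24.1 against 25.9), CORO1A (13.7 against 7.80) and CDH5 (2.23 against 1.23) were present in both libraries, so a small share of such cells stays open. Cells of another epithelial line would not show in these markers, so they stay open at any share. The second lists for interferon-gamma, STAT3 and glucocorticoid responses lay at percentiles 100, 100 and 98.5, as predicted for such responses. The glucocorticoid list decides nothing, since its members also went both ways, with 3 of 9 below 0, and DUSP1 had been seen. Interferon-gamma and STAT3 responses stay hypotheses only, since IRF1 is shared and SAA1, the neighbour of SAA2, had been seen. Whether ASC or another difference between the 2 lines lies behind the higher lists is untested, as each construct has 1 library.

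The heat shock list lay at percentile 0, and it stayed at 0 after the GC trend, at 0 after the length trend and at 0 after neighbouring genes were removed, which argues against a GC content trend, a transcript length trend and a copy-number difference as the whole cause. A lower heat shock factor response was predicted to bring a second list of chaperone and co-chaperone genes below the random range. That list, with 18 compared genes, lay inside the range at percentile 19.3, so the prediction was not met. Its members went both ways, so this miss does not exclude such a response. Below 0 lay 11 of 18 genes, among them HSPA4L (6.19 against 10.2 RPKM), HSPB8 (0.964 against 2.16), DNAJB4 (5.38 against 7.65) and CHORDC1 (log2 ratio -0.31). CCT2 (386.3 against 369.4 RPKM) and 6 others lay above 0. That response stays open, as do culture state at harvest and the added ASC itself, which are untested.

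Counting error alone gave at most 3 genes past 2-fold in 100 simulated pairs, against the 110 observed. The simulation holds no error in assigning reads to transcripts and no difference between library preparations. It therefore speaks to counting error only, and those sources stay open. Few reads of mitochondrially encoded transcripts are listed for either library, with 66.3 and 68.1 reads for MT-CO1 and 52 and 77 for the ribosomal RNA MT-RNR2. Whether such reads were absent from the libraries or left out in processing was not tested.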
